A study of Sus scrofa with 23 samples.

How the data were processed

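Pig bone marrow-derived macrophages were grown from 3 pigs, exposed to lipopolysaccharide (LPS, a bacterial cell wall component) from Salmonella at 100 ng/ml, and sampled at 0, 2, 7 and 24 h. Per the labels, each pig gave a culture and a duplicate culture at each time, except pig 3 at 24 h, which has 1. RNA was hybridized to 23 Affymetrix porcine expression arrays. The deposited values are probe set intensity values on a linear scale, made by the authors with affy and RMA per the submitters' processing notes; the versions of both tools are not given in the sources used here. Signal brightness was already background-corrected and made comparable between arrays by that step. Array medians ran from 69.5 to 73.9 intensity units. For these arrays, their number limits the precision.

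Intensities were converted to log2 and not normalized again. Of 24123 probe sets, 124 array controls were left out of the tests, which left 23999. The platform annotation gave 1 gene for 10069 probe sets, several for 198 and none listed for 13732, and no gene was named from a probe set with several. Symbols were updated through the gene identifier in the RefSeq gene table of the Sscrofa11.1 assembly. Where a gene had more than 1 probe set (2261 of 6765 genes), the one with the highest mean over all arrays stood for the gene. No coordinates are given, because no genome sequence was used here.

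Samples were grouped by their labels. Duplicate cultures were averaged, which gave 12 pig-by-time means, and the pig, not the culture, was the replicate. The comparisons were 2, 7 and 24 h against 0 h, 7 h against 2 h, 24 h against 7 h, and any difference among the times. Each used limma (version 3.58.1, R 4.3.3) with time and pig as terms and 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. The pig term was kept because the series description says that the same pigs supplied every time point. Deviations of these means from the time means correlated within a labelled pig at 0.27 to 0.97 over the comparisons. They were highest for 2 h against 0 h (0.87 to 0.97) and 24 h against 7 h (0.83 to 0.90). Those are the labelled times that the most similar arrays, described below, join in pairs. The other comparisons gave 0.27 to 0.78. The fit used a shared spread per probe set for all comparisons, with no term for those pairs. Its SEs and p-values therefore do not measure the spread of the comparisons made within those pairs. The design had assumed log2 values, and the change of unit altered nothing but the conversion.

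Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, over lists with at least 5 measured members, 24 in all. The lists covered cytokines, chemokines, interferon-stimulated genes, signalling, metabolism, macrophage functions and markers of other cell types. Differences between labelled pigs and the pig-by-time interaction were tested with limma F tests on the 23 arrays unaveraged, with 11 residual degrees of freedom. Peak times were to be counted among genes past the test over all times with at least a 2-fold change. The rule for named genes took the 12 largest changes in each direction against 0 h and 5 for each later step among genes called and moving alike in all pigs, up to 4 called members per list, the 5 smallest p-values for pig and for interaction, and 22 genes fixed in advance.

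The labels were checked with the Y-linked gene EIF1AY and with the similarity of duplicate cultures. After that check, a description that uses no labels was added: the range of each gene over the 23 arrays, and the percentile of each list's median range among 10000 random lists matched on mean expression in 20 bins. Pairs of arrays that were each other's most similar array served there as a guide to measurement noise; they were picked for their similarity, so their differences are a low estimate. For the test of array noise in the closing section, pairs were picked on probe sets outside the genes tested.

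The test of time and the test of pigs were tested on simulated data with 23999 probe sets. For 2 h against 0 h, 79 of 100 probe sets changed by 1 on the log2 scale and 98 of 100 changed by 3 were recovered, with 4 false calls. The changed probe sets were drawn at random from all. These rates therefore do not hold for genes of wide spread such as TNF, whose difference had an SE of 1.51. The pig-by-time means were drawn with independent noise, whereas the real labelled 0 h and 2 h means of a pig moved together. The rates and the 4 false calls therefore do not calibrate the real test of time. For the pig test the figures were 91 and 97 of 100, with 9 false calls. The arrays were drawn there as independent, without the most similar pairs of the real data. Those false calls therefore do not calibrate the real pig test. Alternatives covered the pig term, the use of the cultures, filtering of dim probe sets, renormalization, the variance model, the fold threshold, the choice of probe set, the gene list test and leaving out each pig. A fit without the arrays that went against their labelled sex, and for the labelled pigs a fit with each pair of most similar arrays averaged (12 units, 6 residual degrees of freedom), were added after seeing the data. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.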

Results

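The series asked how gene expression in pig bone marrow-derived macrophages changed over 24 h of exposure to 100 ng/ml LPS. It held 6 arrays labelled 0 h, 6 labelled 2 h, 6 labelled 7 h and 5 labelled 24 h, from 3 pigs. The labels give pigs 1 and 3 as male and pig 2 as female.

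EIF1AY, a translation factor gene on the Y chromosome, went against the labelled sex on 8 of 23 arrays. Its log2 intensity lay between 8.16 and 9.45 on 15 arrays and between 3.60 and 4.08 on the other 8, with none in the gap of 4.08. Of the 8 arrays labelled female, 4 had the high level, and of the 15 labelled male, 4 had the low level, 2 labelled pig 1 and 2 labelled pig 3. A gap of at least 2 on the log2 scale separated the same arrays for 10 probe sets, with that of EIF1AY among them. The Y-linked SRY stayed between 4.13 and 4.56 on every array and separated none.

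**Figure D1:**
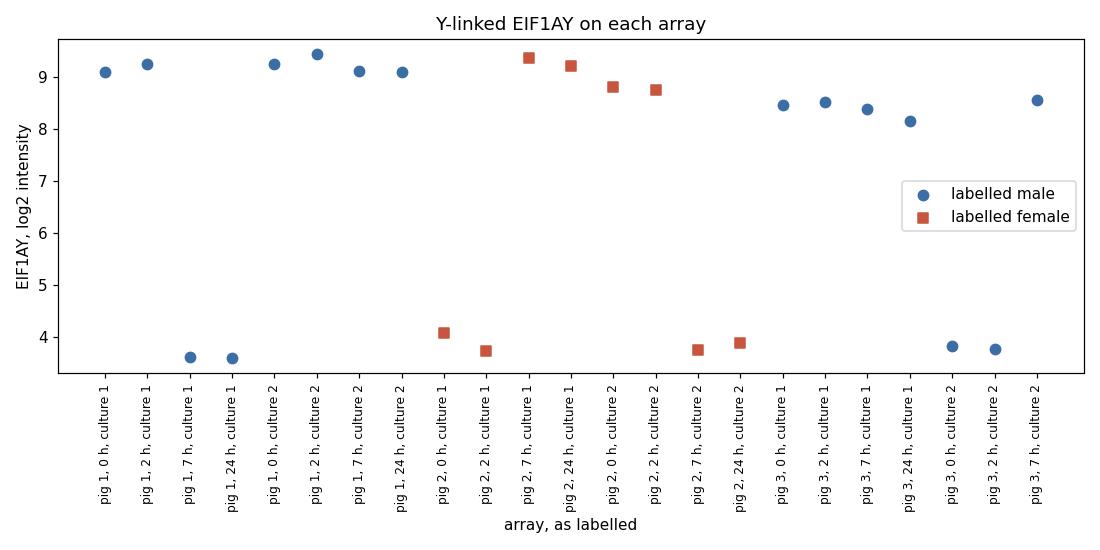
Log2 intensity of EIF1AY (vertical axis) on each of the 23 arrays, named by label (horizontal axis); circles are labelled male and squares labelled female. There are 15 arrays at 8.16 or above and 8 at 4.08 or below, and 8 arrays lie on the side opposite to their labelled sex.

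Duplicate cultures did not resemble each other most. For 0 of 22 arrays with a labelled duplicate was that duplicate the most similar array. The correlation over probe sets between labelled duplicates ran from 0.975 to 0.990 (median 0.977), against 0.987 to 0.998 (median 0.997) for each array's most similar array. There were 11 pairs of arrays that were each other's most similar. All 11 shared the labelled pig and 0 of 11 shared the labelled time. Labelled time accounted for 1.31% of the variance along the leading principal component, which held 46.0% of the total, and labelled pig for 77.6%. Every comparison between times or pigs is therefore given for arrays as labelled, and shows neither an effect of LPS nor its absence.

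**Figure D2:**
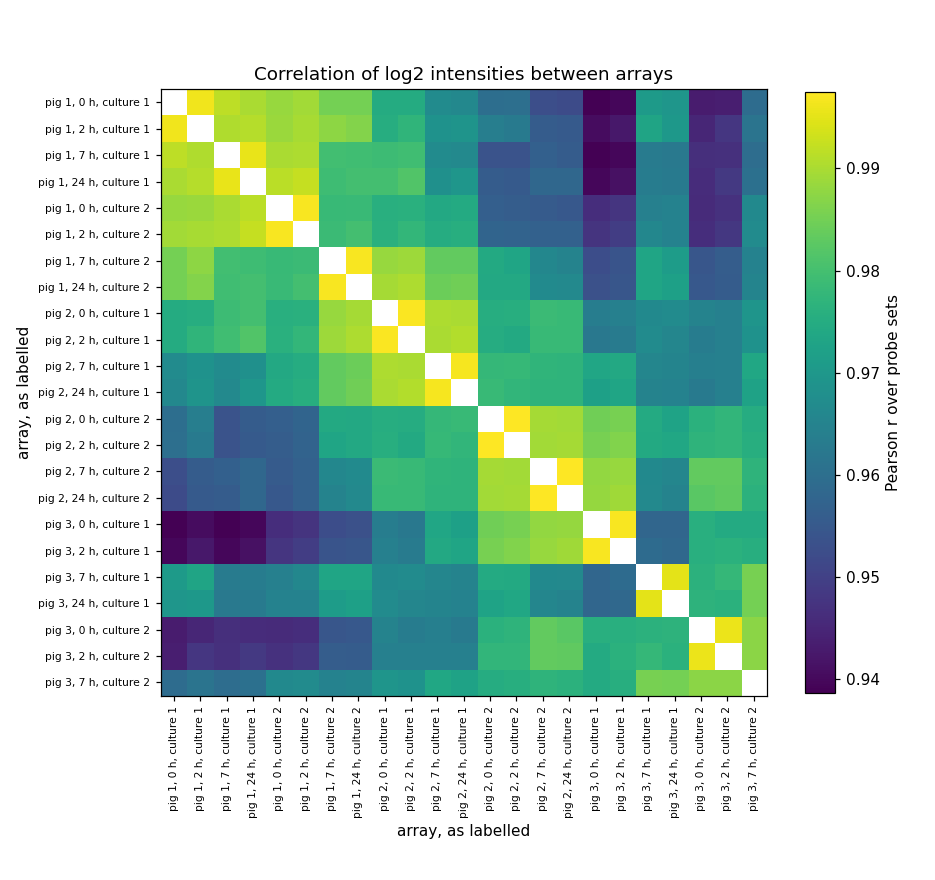
Pearson correlation of log2 intensities over probe sets between every pair of the 23 arrays, named by label on both axes; lighter colours are higher and the diagonal is blank. The brightest cells are 11 pairs of the same labelled pig and different labelled times.

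Between arrays labelled 2 h and 0 h, 3 of 23999 probe sets passed the limma test, all higher at the labelled 2 h. They belonged to IFI30, a lysosomal thiol reductase (0.96 ± 0.09 log2, SE, adjusted p = 0.0261), LAPTM5, a lysosomal membrane protein (0.83 ± 0.08, adjusted p = 0.0387), and RPL12, a ribosomal protein (0.79 ± 0.07, adjusted p = 0.0261). These 3 were named after their values were seen. Other probe sets of the same genes did not pass, with log2 differences of -0.03 for IFI30, -0.06 for LAPTM5, and 0.06 and 0.00 for RPL12. The called probe sets had mean levels of 7.22, 7.95 and 8.30 for IFI30, LAPTM5 and RPL12. The probe sets with the highest mean, which stood for these genes, had 13.56, 12.88 and 13.64. Of the probe sets that stood for a gene, 0 were called. An unadjusted p under 0.05 was reached by 521 probe sets. The count was not stable: it was 0 without any single pig or without the 8 arrays against their sex, 30 with the 23 arrays and pig-by-time as a random block, 28 with culture set added and 19 on these 2 time points only.

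Between the labelled 7 h and 0 h arrays, 0 probe sets passed the limma test, and 754 had an unadjusted p under 0.05. Between 24 h and 0 h, 1 passed, the same RPL12 probe set (0.81 ± 0.07 log2, adjusted p = 0.033), and without the pig block 2 passed. Between 7 h and 2 h that RPL12 probe set differed by -0.81 ± 0.07 (adjusted p = 0.0331), the only call, against 3 without the pig block. Between 24 h and 7 h it was again the only call (0.84 ± 0.07, adjusted p = 0.0253). Over all times, 2 probe sets passed, those of RPL12 (adjusted p = 0.0179) and IFI30 (adjusted p = 0.0386). Leaving out any single pig removed each of these calls. Without the 8 arrays against their sex, 1 probe set passed for 7 h against 0 h, 3 for 24 h against 0 h, 1 for 7 h against 2 h, 0 for 24 h against 7 h and 1 over all times. With the 23 arrays and pig-by-time as a random block, the counts in that order were 0, 15, 28, 21 and 34, and with culture set added 0, 15, 24, 18 and 32. No gene met the criteria for a peak time, at 2-fold, 1.5-fold or 3-fold.

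Of the 22 inflammatory and macrophage genes fixed in advance, 18 had a named probe set, and 0 passed the limma test in any comparison, with adjusted p from 0.914 to 1; 0 passed when adjusted over the list alone. TNF, a cytokine released by activated macrophages, had a log2 intensity of 9.35 ± 3.06 (SD, n = 3 labelled pigs) at the labelled 0 h and 9.23 ± 3.11 at 2 h. IL1B, another inflammatory cytokine, stood at 11.89 ± 3.58 and 12.05 ± 3.25. TNF had an SE of 1.51 in every comparison, although the most similar pairs differed in it by a median of 0.09. These pairs join labelled 0 h with 2 h and 7 h with 24 h. For those comparisons the SEs and adjusted p therefore do not measure the spread within pairs. The largest difference from 0 h was -1.09 for IL12B at 24 h (SE 0.89, adjusted p = 0.914), less than its SD of 2.64 between labelled pigs at 0 h; it was -1.89 without pig 1, -1.77 without pig 2 and 0.40 without pig 3, and 0.30 with the duplicate cultures only. NOS2, the inducible nitric oxide synthase, stayed between 5.66 and 6.24 on all arrays.

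**Figure D3:**
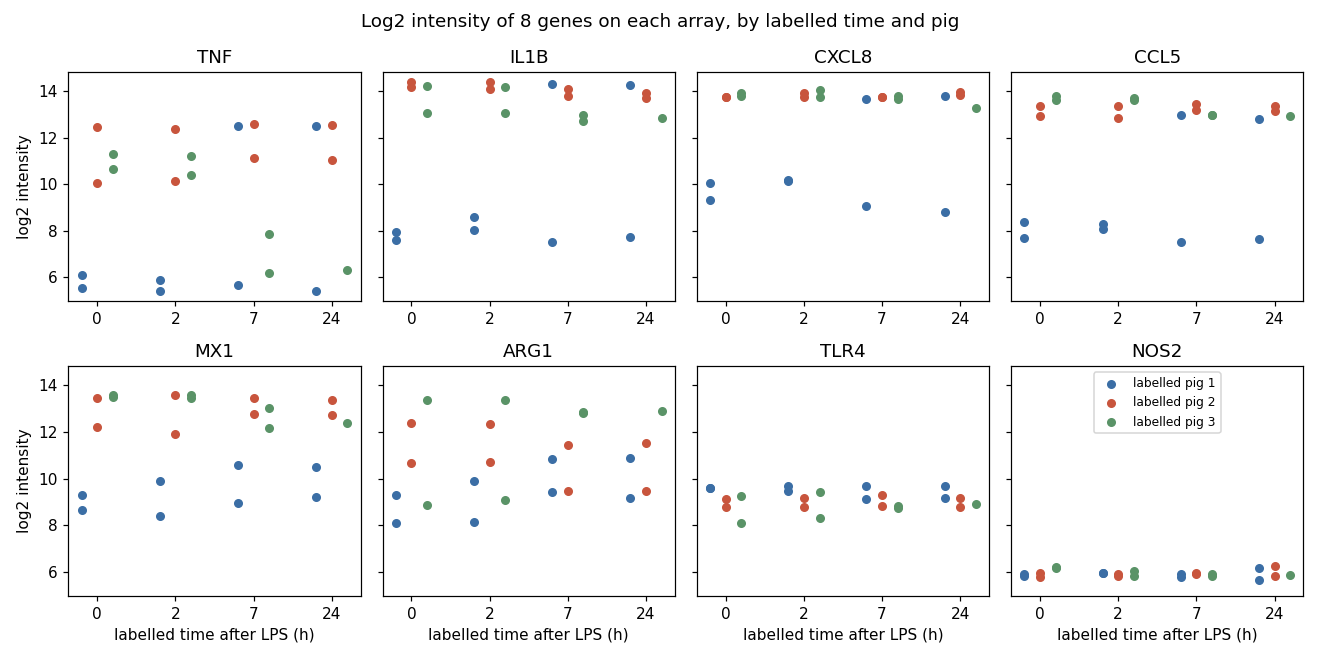
Log2 intensity (vertical axes) of 8 genes on each array against labelled time in hours (horizontal axes, evenly spaced categories), coloured by labelled pig; each point is 1 array. TNF and IL1B span 7.14 and 6.84 log2 units over the arrays, at labelled 0 h as well as later, and NOS2 spans 0.58.

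Among 24 gene lists, camera called 1 for the labelled 2 h against 0 h: granulocyte and precursor markers were higher (median 0.13 log2, 8 genes, adjusted p = 0.00664), with an adjusted p of 0.974 with an estimated correlation. For 24 h against 0 h it called glycolysis and hypoxia genes, higher by a median of 0.21 (20 genes, adjusted p = 0.00947, and 0.706 with an estimated correlation). For 24 h against 7 h it called 4 lists. Markers of T and NK cells (median 0.09, 12 genes), stromal cells (0.28, 16 genes) and granulocytes (0.22, 8 genes) were higher, with adjusted p of 0.00261, 0.00261 and 0.0428, each with an adjusted p of 0.74 with an estimated correlation. Antigen presentation genes were lower by a median of -0.15 (22 genes, adjusted p = 0.0428, and 0.873 with an estimated correlation). For 7 h against 0 h and 7 h against 2 h, 0 lists passed, but 1 to 9 and 4 to 9 passed when a labelled pig was left out, and 12 and 9 without the 8 arrays against their sex. At 24 h against 0 h, 6 to 7 passed without a pig and 11 without the 8 arrays, and at 24 h against 7 h, 1 to 8 and 3. At 2 h against 0 h, 1 list passed in each of these fits. No list member passed over all genes. Adjustment over the list alone was made separately for each of the 24 lists in each comparison, so such calls can arise by chance. The members named next had an adjusted p of 0.914 or higher in the limma test over all probe sets. Adjusted over the list alone, CXCL16 passed at 7 h against 0 h (0.37) and against 2 h (0.36), SIGIRR at 24 h against 7 h (0.32), and NFATC1 at 24 h against 0 h (0.39). Without the pig block, 0 lists passed at 2 h against 0 h, 1 at 7 h against 0 h, 1 at 24 h against 0 h, 0 at 7 h against 2 h and 2 at 24 h against 7 h.

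Interferon-stimulated genes differed between labelled pigs: 26 of 26 passed the limma F test, and all 26 had their lowest mean in labelled pig 1. CXCL9, a chemokine induced by interferon gamma, had a mean log2 intensity of 5.02 ± 0.70 (SD, n = 8) in labelled pig 1, 11.49 ± 1.41 (SD, n = 8) in pig 2 and 12.87 ± 1.10 (SD, n = 7) in pig 3, with an adjusted p of 7.05e-07. The antiviral gene RSAD2 had 9.02, 13.73 and 13.71, and USP18, a negative regulator of interferon signalling, had 8.02, 11.85 and 12.06. IRF9, a transcription factor of the interferon response, had 7.74, 8.89 and 9.19, and ARAP2 had 5.69, 7.94 and 7.98. These 4 had an adjusted p of 1.12e-05. In all, 8875 of 23999 probe sets passed, among them 12 of 14 chemokines, 12 of 17 inflammatory cytokines, 19 of 22 antigen presentation genes and 20 of 20 mitochondrial genes. So did 11 of 15 negative regulators of LPS signalling, 13 of 20 glycolysis and hypoxia genes and 11 of 17 cell death genes. Among cholesterol and lipid genes 14 of 22 passed, and among toll-like receptor signalling genes 11 of 19. Shares were smaller for immediate-early (7 of 20), arginine and nitric oxide (7 of 19) and cell cycle genes (9 of 24). Among endothelial markers 1 of 8 passed, and among stromal markers 0 of 16. The lists did not all move alike: 0 of 20 mitochondrial genes had their lowest mean in labelled pig 1. The pig-by-time interaction was called for 1 probe set, FGL2 (adjusted p = 0.0154). Without the 8 arrays against their sex, 15 arrays remained for the 12 pig-by-time groups. Most groups then held 1 array, so nothing is concluded from the interaction in that fit. Its count is listed only among the alternatives below. Agreement with the labelled sex also does not show that the other labels of those arrays hold. The F test took the 23 arrays as separate units although 22 of them form pairs of most similar arrays, so its p-values are too small. With each pair averaged to 1 unit (12 units, chosen after seeing the data), 2872 probe sets passed, among them 21 of 26 interferon-stimulated genes, 5 of 14 chemokines, 4 of 17 inflammatory cytokines, 10 of 22 antigen presentation genes and 11 of 20 mitochondrial genes. The adjusted p of CXCL9, RSAD2, USP18, IRF9 and ARAP2 was then 0.0153. Each averaged pair merges labelled 0 h with 2 h or 7 h with 24 h, so that fit holds only an interaction of pig with 2 time classes, for which 0 probe sets passed, and not the interaction with 4 times. Since each labelled pig held arrays with both EIF1AY levels, these are differences between arrays under those labels and cannot be read as differences between animals.

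Set without labels, the arrays differed widely in inflammatory genes. Of 6765 genes, 897 (13.3%) spanned at least 2 log2 units over the 23 arrays and 153 spanned at least 4, where the median gene spanned 0.96. Chemokines had the highest median span, 5.40 log2 units, with 12 of 14 members spanning at least 2; CXCL9 ran from 4.18 to 13.93. Interferon-stimulated genes had a median span of 4.75, with 25 of 26 members at 2 or more, and OAS1 ran from 4.20 to 12.24. Inflammatory cytokines had a median span of 4.11, with 12 of 17 members at 2 or more; TNF ran from 5.42 to 12.56 and IL1B from 7.53 to 14.37. The 11 most similar pairs differed in TNF by a median of 0.09 and at most 0.27, in IL1B by a median of 0.08 and at most 0.99, in CXCL9 by at most 0.28, in OAS1 by at most 0.78 and in RSAD2 by at most 1.41. Prostanoid, coagulation and matrix genes had a median span of 3.47, granulocyte markers 3.34 and antigen presentation genes 2.55. None of 10000 matched random lists reached the median span of these 6 lists. In all, 12 of 26 lists lay above percentile 99.

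Of the lists above that percentile, cell death genes had a median span of 1.93, negative regulators of LPS signalling 1.82, cholesterol and lipid genes 1.70, toll-like receptor signalling 1.66, immediate-early genes 1.63 and complement 1.61. Lists below it were dendritic cell markers (2.58, from 2 genes), osteoclast markers (2.08), stromal markers (1.40), tryptophan catabolism (1.37), glycolysis and hypoxia (1.36), B and plasma cell markers (1.17), cell cycle (1.17), iron and oxidant handling (1.15) and mitochondrial respiration (1.09). Arginine and nitric oxide metabolism had a median span of 1.00, near that of its random lists at 1.02, although ARG1, the urea cycle arginase, ran from 8.09 to 13.37. Macrophage and lysosome genes (0.83), endothelial markers (0.77), erythroid and platelet markers (0.68) and T and NK cell markers (0.68) spanned no more than matched random lists.

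**Figure D4:**
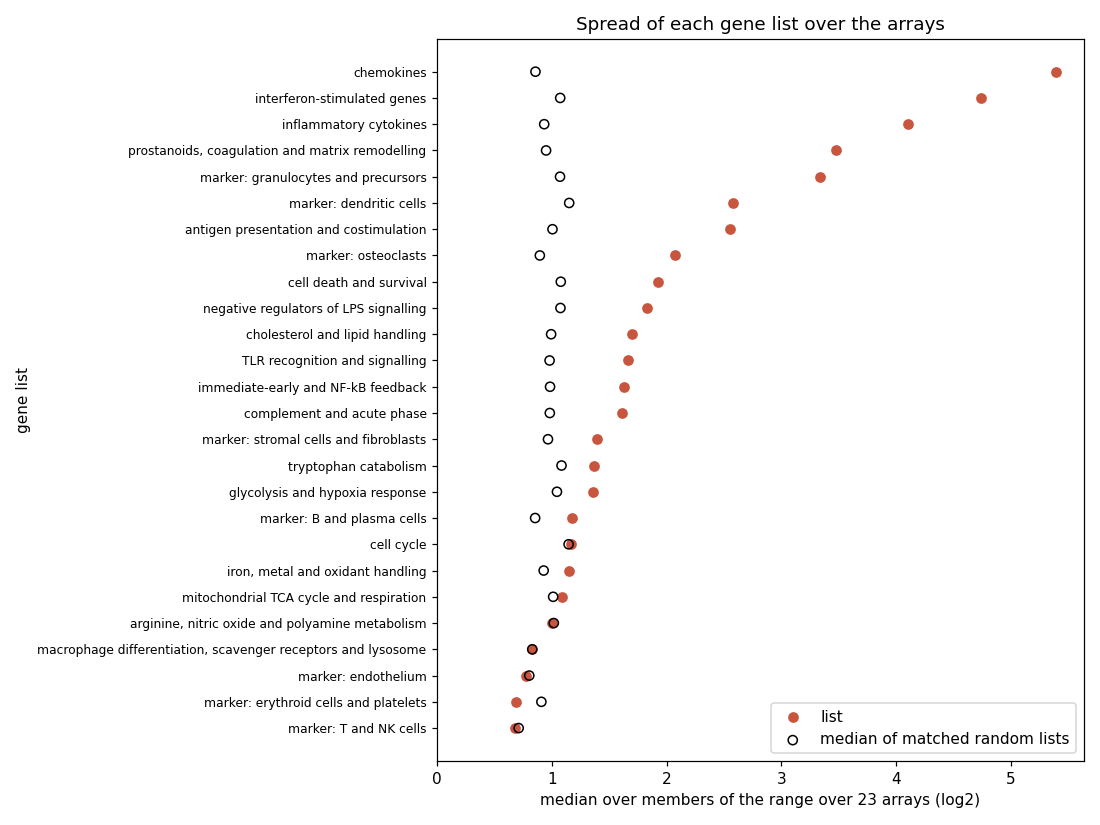
Median over list members of the range of log2 intensity over the 23 arrays (horizontal axis) for each of 26 gene lists (vertical axis); filled points are the lists and open points the median of matched random lists. Chemokines lie at 5.40 and interferon-stimulated genes at 4.75, against 0.86 and 1.07 for their random lists.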

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

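In this part, the tests of the labels, of array noise and of the alternation, and the regroupings that keep pairs together, were chosen after the results were seen; the other counts over splits were planned. Among 76 combinations of gene and labelled time, 9 had 1 array apart from the others, where chance gives about 3.8 if the combinations are independent. They are not: all 9 came from 4 arrays, which form 2 pairs of most similar arrays, so the excess over chance is not interpretable. At the labelled 7 h, the array of pig 1, culture 1 was low for IL1B (7.53, others 12.70 to 14.28), CXCL8 (9.05, others 13.66 to 13.79), CCL5 (7.52, others 12.96 to 13.43) and SOD2 (12.36, others 13.63 to 14.05). At the labelled 24 h, the array of pig 1, culture 1 was low for IL1B (7.72, others 12.85 to 14.26), CXCL8 (8.80, others 13.25 to 13.94) and CCL5 (7.64, others 12.81 to 13.37). CD163, a scavenger receptor of macrophages, was low on the array of pig 3, culture 1 at 0 h (7.85, others 9.29 to 9.91). It was also low on that pig's culture 1 array at 2 h (8.03, others 9.20 to 9.86). The arrays of pig 1 named here were among the 8 with EIF1AY against the labelled sex, and those of pig 3 were not. Effects also differed between times for the RPL12 probe set, by -0.81 between 7 h and 2 h and 0.84 between 24 h and 7 h.

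Inflammatory genes spanned a wide range over the arrays while 0 of 18 fixed genes differed between labelled times. Noise that differs from array to array would leave any pairing of arrays equally far apart in these genes. In 11 pairs chosen on other probe sets, the 65 cytokine, chemokine, interferon-stimulated and fixed genes differed by a median of 0.0892 log2 units, against a median span of 4.72, and the lowest of 10000 random pairings gave 0.32, which argues against such noise. Values standing under the wrong labels may account for the pattern: 8 arrays had EIF1AY levels against their labelled sex. Whether the cells responded to LPS cannot be told from the labels, because they failed that check, and the count of 0 decides nothing. Some genes did differ between runs of neighbouring columns. TNF lay between 5.4 and 6.1 on columns 1 to 6 and between 12.3 and 12.6 on columns 7 to 12. IL1B lay between 7.5 and 8.6 and between 13.7 and 14.3 on the same columns. NOS2, IL6 and CD163 were among the genes that overlapped between them. These columns were picked after the levels were seen, so no response is concluded.

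The EIF1AY levels themselves argue against a wrongly recorded sex of an animal, since all 3 labelled pigs held both levels. A candidate explanation is that the columns were ordered by time, then pig, then culture, while the labels were listed by pig. Under that order, 23 of 23 arrays would have the EIF1AY level of their pig, and the best of the other 5 nestings of those labels matched 15. The 11 pairs of most similar arrays would all be duplicate cultures under that order, as they would under pig, then time, then culture, against 0 as labelled. If the 23 arrays were independent, a random order would match all with probability 2.04e-06. They are not, since both arrays of each most similar pair had the same EIF1AY level. That probability is therefore too small, and none was computed with the pairs kept together. This order was also chosen after the levels were seen. This order would place columns 1 to 6 at the same time point and columns 7 to 12 at another. The sex gene leaves the order of the times open, and no test of time was made under this order.

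The called probe sets of RPL12, IFI30 and LAPTM5 alternated between neighbouring columns: for all 3, every array labelled 2 h or 24 h lay above every array labelled 0 h or 7 h. From the labels, an alternation unrelated to time and an effect of labelled time cannot be told apart, because the design places both on the same arrays. Under the candidate order above, the arrays of each pair would be duplicate cultures of the same pig and time. The alternation would then lie between first and duplicate cultures and not between times, which was not tested.

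For the comparisons of labelled times there were 10 splits of the 6 pig means, too few for a share under 0.05. The real counts of probe sets were 3 for 2 h against 0 h, 0 for 7 h against 0 h, 1 for 24 h against 0 h and 1 for 7 h against 2 h, where 1, 10, 1 and 1 of 10 splits gave as many and the highest other count was 0 in each. For 24 h against 7 h the real count was 1, 2 of 10 splits gave as many, and the highest other was 4. For gene lists, in the order 2, 7 and 24 h against 0 h, 7 h against 2 h and 24 h against 7 h, the real counts were 1, 0, 1, 0 and 4. As many came from 7, 10, 9, 10 and 5 of 10 splits, with highest other counts of 11, 9, 11, 7 and 10. Over all times, 7 of 100 regroupings within pigs gave 2 probe sets or more (highest other 10), so chance was not excluded. For the labelled pigs, 1 of 100 regroupings gave 8875 or more (highest other 2075), and for the pig-by-time interaction 13 of 100 gave 1 or more (highest other 347). These regroupings parted the pairs of most similar arrays, which lowers the pig counts, so they decide nothing. Each count out of 100 or 10 includes the real grouping. With the pairs kept together, 1 of 100 regroupings, the real one, gave 8875 or more (highest other 5294). The labelled pigs thus differed by more than scattered groupings of pairs. Each labelled pig is also a run of neighbouring columns, which the regroupings did not keep. They cannot tell a difference between labelled pigs from a difference between runs of columns. For the interaction 36 of 100 gave 1 or more (highest other 2428), so chance was not excluded.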

How the results depend on the processing

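The alternatives were fixed before the data were examined, except the fit without the arrays against their labelled sex and the fit on averaged pairs, which were chosen after seeing the data. For the 18 fixed genes, 540 alternative values gave 0 past the threshold, with adjusted p from 0.0725 to 1. Probe set counts for 2, 7 and 24 h against 0 h, 7 h against 2 h, 24 h against 7 h and any time were 3, 0, 1, 1, 1 and 2. They became 30, 0, 15, 28, 21 and 34 with 23 arrays and pig-by-time as a random block, and 28, 0, 15, 24, 18 and 32 with culture set added. They were 0 in all 6 with either culture set alone, with trend and robust variance, with a 2-fold minimum, with 1 probe set per gene, and, as the range from 0 to 0, without each pig. Repeated quantile normalization gave 0, 0, 0, 1, 1 and 1, and centring left 1 for any time. Fits on 2 time points gave 19 for 2 h against 0 h and 0 for the other 4. Without the 8 arrays against their sex the counts were 0, 1, 3, 1, 0 and 1. Without the pig block they were 2, 0, 2, 3, 1 and 3, so the pairing moved 4 of the 6 counts, those for 24 h against 0 h and 7 h against 2 h by over 1.5 times. The cause was not tested, except that the culture sets, single pigs and stricter criteria use fewer samples or genes.

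Gene list counts were 1, 0, 1, 0 and 4. They were 0 in all 5 with an estimated correlation and with fry. Without the pig block they were 0, 1, 1, 0 and 2. Cultures numbered 1 alone gave 0, 1, 2, 1 and 2, and cultures numbered 2 alone 1, 3, 6, 3 and 5. Without dim probe sets they were 1, 0, 1, 2 and 2, and with the mean over probe sets 24 h against 7 h had 2. Leaving out each pig gave 1 to 1, 1 to 9, 6 to 7, 4 to 9 and 1 to 8. Without the 8 arrays they were 1, 12, 11, 9 and 3. For labelled pigs, counts ran from 6721 to 9313 against 8875, and fell to 2872 with most similar pairs averaged, where fewer units enter. The interaction rose from 1 to 3 without dim probe sets, to 3 with culture set as a term, and to 1384 without the 8 arrays, and was 0 with pairs averaged, for an interaction with 2 time classes; the cause was not tested. The fit without the 8 arrays kept 15 arrays for the 12 pig-by-time groups, and most groups held 1 array. Its interaction count is therefore not comparable with the main count, and nothing is concluded from it. Peak time stayed at 0 in every alternative run. The duplicate set has no array of pig 3 at 24 h. Arrays give no counts, and their number limits the precision.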

Other observations

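All values in this part were chosen after the data were examined, and none uses the labels. Some markers of lymphocytes varied widely while others stayed low. IL7R, the interleukin 7 receptor, ran from 4.91 to 10.98 log2 units over the 23 arrays and CD2, an adhesion molecule, from 5.18 to 10.45. The T cell receptor components CD3E and CD3D stayed between 4.21 and 4.99 and between 5.61 and 6.31. Among stromal markers, LUM, the matrix proteoglycan lumican, ran from 3.23 to 9.38 and COL6A3, a collagen chain, from 5.59 to 10.14, while COL1A2, another collagen chain, stayed between 6.80 and 7.42. All 8 measured granulocyte markers spanned at least 2 log2 units, with LTF, lactoferrin, running from 4.65 to 9.18.

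Other genes with wide spans lay outside the fixed lists. PLAC8 ran from 4.97 to 13.96, CYP3A29, a cytochrome P450, from 4.14 to 12.69, UBD, a ubiquitin-like protein, from 4.66 to 12.29, and STEAP4, a metalloreductase, from 4.10 to 11.55. AOAH, an enzyme that deacylates LPS, ran from 6.27 to 12.93. Of the 124 array control probe sets, which were left out of every test, 4 spanned at least 2 log2 units, by 7.33, 7.03, 4.20 and 2.03.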
